A study of Mus musculus with 6 samples.

How the data were processed

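Ribosome-bound, polyadenylated RNA was measured in 6 mouse liver samples, 3 from mice injected with a plasmid carrying a non-targeting guide and 3 with a guide against Neurl1b. Per the labels' protocols, the mice received 10 µg of plasmid together with a Cre-expressing adeno-associated virus, had been kept on 7.5 µg/mL nitisinone, and were sampled 4 weeks after injection. Per the same protocols, 400 mg of liver was lysed, ribosomes were pulled down with an antibody to GFP, and libraries were made from poly(A)-selected RNA. The guide and the mouse number were taken from the sample titles.

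The deposited values are TPM (shares of a library, corrected for transcript length) for 117486 transcripts in a table of the whole series, with a gene symbol beside each transcript. Per the submitters' processing notes, the tool was kallisto, which assigns reads to transcripts without a genome alignment, and the genome build was mm39. The version of kallisto, the transcript set and any filter are not given in the sources used here. Each column sums to between 999999.8 and 1000000, so TPM keep no depth. The precision of a low value cannot be derived from them, and no counting interval is given. Because TPM are shares of a total, a change in a few abundant genes moves all others, and kallisto divides reads between near-identical transcripts by estimation, so paralogs and pseudogenes are uncertain.

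Transcripts were summed by gene symbol. The 168 transcripts without a symbol held 116 to 143 TPM per library and were left out. Of 35970 symbols, 21941 had a TPM above 0 in any library and 10598 had a mean TPM over the 6 libraries of at least 1. These were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trended prior, two-sided, Benjamini-Hochberg adjusted p below 0.05), for Neurl1b CRISPRi minus non-targeting with no covariate. A fold change on this scale understates the change of low genes. Folds called "-fold" are ratios of mean TPM. Neurl1b, below the filter, was taken from the same fit without the filter, which the plan did not foresee. Gene lists were tested with camera of limma at a preset correlation of 0.01 for 42 lists with at least 5 tested members, adjusted over the lists, and again with an estimated correlation and with fry. camera compares a list with the other genes, and fry tests whether its genes move, on balance, in one direction. Beside each list, members were counted over all genes and adjusted over the list alone. Means of list members per library, and other single values, were compared by exact two-sided permutation, where 3 against 3 cannot go below p = 0.1.

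The rule for named genes, the lists, the tests and the alternatives were fixed before the data were examined, apart from the use of unfiltered fits for Neurl1b. Named are Neurl1b, Fah and Rpl10a, and the 12 genes with the largest and the 12 with the smallest log2 fold change among those past the threshold whose groups do not overlap. Predicted genes are left out of these and only counted, and where fewer than 12 passed the places were filled by the smallest unadjusted p in that direction. Also named are up to 4 members of each list with the smallest p, the Notch list members and the sex-linked genes, except that some genes this rule takes are not reported here. Gm9385 falls outside the rule and was chosen after its values were seen, because only 2 genes passed. The alternatives were a pseudocount of 0.1 or 5, no filter or a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, and TPM rescaled without the 10 most abundant genes, mitochondrial genes, Fah and Rpl10a. Further ones were a constant or a robust prior, array weights, the mouse number as a replicate block, each mouse left out in turn, a transcript-level test, an adjusted p of 0.1, a minimum log2 fold change of 1, and summed TPM of cell type markers.

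The tests were first run on simulated data for this comparison, drawn for the 10598 genes from their means and spreads with 200 genes changed, in 5 draws. limma recovered 2.39% of the genes changed 1.5-fold, 44.5% of those changed 2-fold and 83.0% of those changed 4-fold, with 5.48% false calls among all calls. Here the folds are of TPM + 1, which for low genes is a larger fold of TPM. The simulation has independent genes, so it does not reproduce correlation between genes. Transcript similarity was searched with blastn 2.17.0 against the GENCODE vM21 transcripts (GRCm38), in which 99.04% of the deposited transcript identifiers were found. That annotation is of another build than the table, so it served only for gene order, gene types and sequence similarity, and no coordinates are given.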

Results

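The series profiled ribosome-bound mRNA of hepatocytes that were repopulating an injured mouse liver. The recipient mice lacked Fah, the last enzyme of tyrosine breakdown, and could express dCas9, a cleavage-dead Cas9 that blocks transcription where a guide RNA places it (CRISPR interference, CRISPRi). Injected transposon plasmids gave some hepatocytes Fah, a GFP-tagged ribosomal protein L10a and a guide RNA, and withdrawal of nitisinone left cells without Fah at a disadvantage. Livers were taken 4 weeks later, and ribosomes carrying the tag were pulled down with an antibody to GFP (translating ribosome affinity purification, TRAP). There were 6 libraries from separate mice, 3 with a non-targeting guide and 3 with a guide against Neurl1b. The p-values of single genes and of the permutation tests therefore measure the spread between mice. The values were TPM, shares of a library corrected for transcript length and scaled to a total of 1000000, which keep no depth, so the number of reads behind each library is unknown. After transcripts were summed by gene symbol, between 17813 and 18680 genes had a TPM above 0 in a library, and 10598 genes with a mean TPM of at least 1 were tested.

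The targeted gene was measured first. Neurl1b encodes an E3 ubiquitin ligase that acts on Notch ligands. Its TPM was 1.22, 0.897 and 0.688 in the non-targeting mice and 0.295, 0.351 and 0.307 in the Neurl1b CRISPRi mice. The means were 0.936 ± 0.270 and 0.317 ± 0.029 (SD, n = 3 each), so that the CRISPRi level was 33.9% of the control level, or 2.95-fold lower. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 allows. In limma without the filter on low values, which Neurl1b did not pass, the log2 fold change of TPM + 1 was -0.55 (SE 0.11, unadjusted p = 0.00335, adjusted p = 0.430 over 21941 genes). All of this signal came from transcript ENSMUST00000053020.8, while the remaining 2 Neurl1b transcripts were at 0 in every library. The precision of levels this low is unknown.

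**Figure D1:**
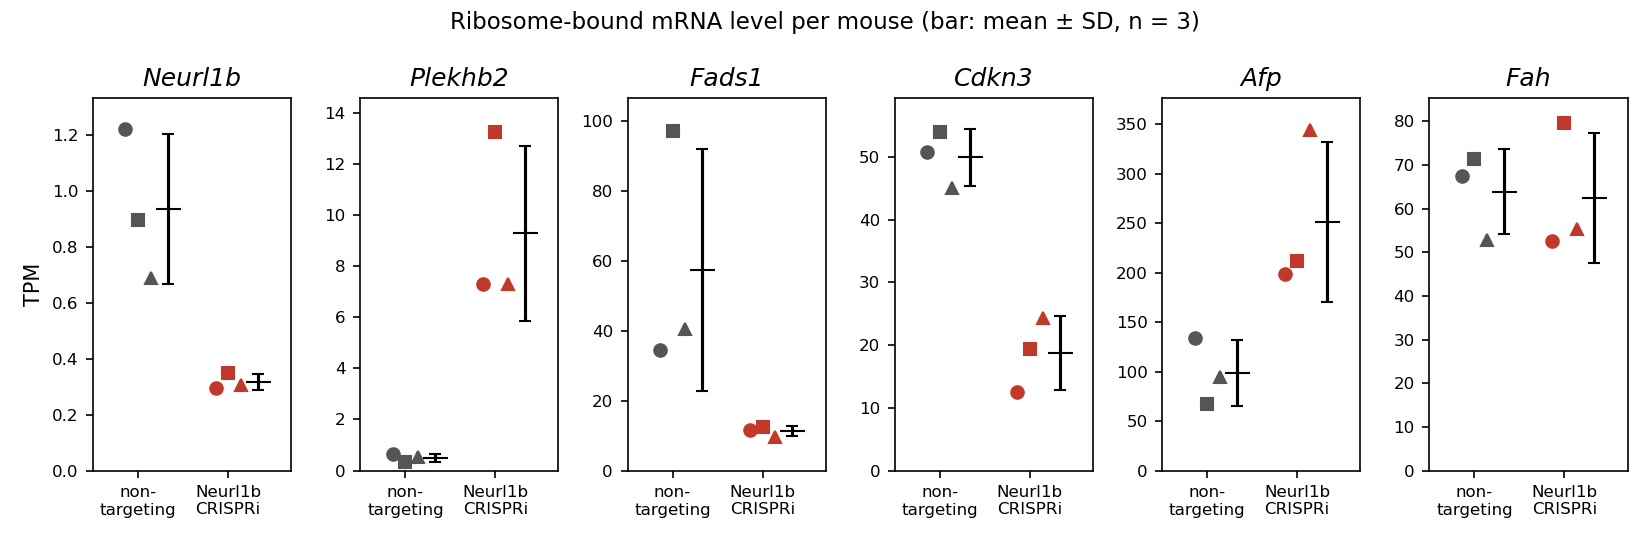
TPM per mouse (vertical axes, linear from 0) of the targeted gene Neurl1b, of Plekhb2, Fads1, Cdkn3 and Afp, and of Fah, in the non-targeting and Neurl1b CRISPRi groups; symbols are single mice (circle 1, square 2, triangle 3) and bars the mean ± SD of 3. Neurl1b lies between 0.688 and 1.22 in the controls and between 0.295 and 0.351 in the CRISPRi mice, and the groups overlap for Fah alone.

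The comparison of all genes asked what changed in the ribosome-bound mRNA when Neurl1b was repressed. Plekhb2, which encodes a pleckstrin homology domain protein of endosomal membranes, rose from a mean TPM of 0.499 ± 0.155 to 9.30 ± 3.43 (SD, n = 3 each), an 18.6-fold difference. Its log2 fold change was 2.74 (SE 0.24, limma adjusted p = 0.0123). The predicted gene Gm9385 also passed, with a TPM of at most 0.00261 in the controls and of 12.1, 5.52 and 13.7 in the CRISPRi mice. It is annotated as a processed pseudogene and its 472-nt transcript is 99.8% identical to Rpl24, so its level is uncertain. These 2 genes were the only ones past an adjusted p of 0.05 in limma, and neither passed when non-targeting mouse 3 was left out (adjusted p = 0.226 for both), while each passed in the fits that left out any other mouse. No gene passed in the lower direction, where the smallest adjusted p was 0.0985. At an unadjusted p below 0.05 there were 1408 genes (13.29% of those tested), 1070 higher and 338 lower in the CRISPRi mice. In 1807 genes (17.05%) the groups did not overlap, against 10% by chance. The median log2 fold change of all tested genes was 0.18 and became -0.0013 with median-of-ratios scaling of the libraries, so a change is best read relative to that shift.

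The count of changed genes depended on single control mice. Without non-targeting mouse 3, 0 genes passed in limma and 920 had an unadjusted p below 0.05. Without non-targeting mouse 1, 2673 genes passed in limma, 2436 higher and 237 lower. With median-of-ratios scaling as well, chosen after seeing the data, 480 passed, 189 higher and 291 lower. Across genes, the log2 values of this mouse had correlations of 0.982, 0.987 and 0.986 with the 3 CRISPRi libraries, and of 0.965 and 0.974 with non-targeting mice 2 and 3. Genes are not independent replicates, so these correlations carry no test. Mitochondrially encoded genes had a list mean of 5.58 on the log2 scale in this library, against 6.32 to 7.01 in the other 5.

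**Figure D2:**
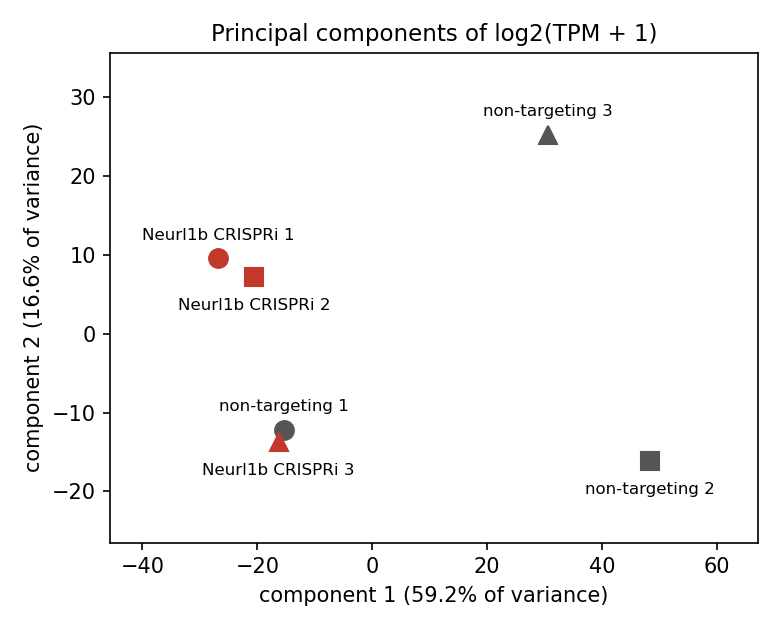
First and second principal component of log2(TPM + 1) over the 10598 tested genes; each point is a mouse, coloured by group. Non-targeting mouse 1 lies at -15.3 on the first component (59.2% of the variance), next to the CRISPRi mice, which lie between -26.8 and -16.3, while non-targeting mice 2 and 3 lie at 48.3 and 30.7.

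Besides Plekhb2, the genes with the smallest p in each direction did not pass the adjusted threshold. Choosing by p favours genes whose groups do not overlap, a trait of 17.05% of all tested genes. It held for each of the genes chosen here, so it adds no support for them. Those with more TPM in the CRISPRi mice were Dynlt2a1, Hid1, Rhof, Reln, Rtl8c, Zpr1, Treh, Dusp3, Adm, Akr1b8 and Abcg1, with adjusted p of 0.216 to 0.259. Hid1 had a mean TPM of 4.66 ± 0.313 against 1.10 ± 0.711 in the controls. The phosphatase gene Dusp3 had 34.4 ± 1.41 against 15.8 ± 5.04, and the trehalase gene Treh had 2.80 ± 0.162 against 1.20 ± 0.126 (SD, n = 3 each). Those with less TPM were Rps24-ps3, Nat8, Cyp2d38-ps, Serpinb8, Egr1, Apon, Cyp4f14, Cyp2j5, Cdkn3, Fads1, Sult2a5 and Nat8f2, with adjusted p of 0.0985 to 0.242. The fatty acid desaturase gene Fads1 had a mean TPM of 11.3 ± 1.52 against 57.4 ± 34.6. The immediate early transcription factor gene Egr1 had 2.53 ± 0.646 against 9.34 ± 2.69, and the arachidonic acid epoxygenase gene Cyp2j5 had a mean TPM 5.34-fold lower (log2 fold change -2.29, SE 0.38). Cdkn3, a cell cycle phosphatase gene, had one 2.67-fold lower (log2 fold change -1.41, SE 0.24). Rps24-ps3 and Cyp2d38-ps are named as pseudogenes and can share reads with their parent genes.

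Of the 42 gene lists, 18 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01. Of these, 12 were lower and 6 higher relative to the other genes. That preset treats the members of a list as nearly independent, so these p-values do not measure the spread between mice. Estimated correlations within the lists ranged from 0.0157 for female-biased to 0.802 for mitochondrially encoded genes, with 0.797 for mitosis. None of the 42 passed with an estimated correlation (camera, lowest adjusted p = 0.152, 3 lists at an unadjusted p below 0.05) or in fry (lowest adjusted p = 0.212, 3 lists at an unadjusted p below 0.05). Adjusted over the list alone, 76 list memberships in 15 lists passed in limma, although no list member passed over all genes tested. That adjustment does not account for the number of lists tried, and some genes belong to several lists. Without non-targeting mouse 1, members passed over all genes, among them 5 mitosis, 9 plasma protein, 11 male-biased and 7 female-biased genes, all lower, and 11 YAP targets, 11 p53 targets and 14 genes of the unfolded protein and integrated stress response list, all higher. In that fit 2436 of 10558 genes passed as higher and 237 as lower. Lists that camera did not call also had high counts, with 15 of 36 ribosome biogenesis and 14 of 32 endocytosis and ubiquitin genes higher. With all mice and median-of-ratios scaling, every list median shifted by between -0.098 and -0.22.

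Genes of mitosis were the lowest of the lists by p. Their median log2 fold change was -0.70, 34 of 36 tested members were below 0, and the groups did not overlap for 22 members, all lower in the CRISPRi mice. Adjusted over the list alone, 15 of 36 passed, all lower, and none passed over all genes. Birc5, which encodes survivin, had a mean TPM 2.61-fold lower (log2 fold change -1.37, SE 0.25), and Knstrn, a spindle gene, 2.96-fold lower (-1.55, SE 0.30). The mean TPM of the spindle genes Hmmr and Racgap1 was 2.41-fold and 2.43-fold lower. The adjusted p of the list was 2.44e-31 in camera and 0.386 with an estimated correlation. The list means were highest in non-targeting mouse 1, at 3.69 on the log2 scale, against 2.99 and 3.01 in the other control mice and 2.13 to 2.81 in the CRISPRi mice (exact two-sided permutation p = 0.1). The DNA replication list did not pass (adjusted p = 0.417) except, in the lower direction, without non-targeting mouse 2 or without CRISPRi mouse 3, with a median of 0.20 that became -0.0048 with median-of-ratios scaling, and 24 of 38 members above 0. Without non-targeting mouse 1 the median of this list was 0.42. Its members with the smallest p went both ways, with log2 fold changes of -0.95 for Tk1, -0.78 for Mcm10, 0.63 for Chaf1a and 0.62 for Cdt1.

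Lipid synthesis lists were also called lower in camera. Cholesterol synthesis had a median log2 fold change of -0.46 with 23 of 25 members below 0, and fatty acid synthesis had -0.24 with 24 of 29 below 0. Adjusted over the list alone, 3 genes passed in each, all lower. Among them Fads2 and Fads1, desaturases of polyunsaturated fatty acids, had log2 fold changes of -1.03 and -2.10. The sterol genes Tm7sf2, Ebp and Sc5d had -0.96, -0.67 and -0.71. Thrsp, a lipogenic regulator, had -1.78 and Agpat2 had -0.62. The camera adjusted p was 2.50e-14 for cholesterol and 1.32e-10 for fatty acid synthesis, and with an estimated correlation the adjusted p was 0.386 and 0.364. The means of the cholesterol list overlapped between the groups, with 5.28 in non-targeting mouse 3 and 5.44 in CRISPRi mouse 1 (exact two-sided permutation p = 0.2). Its median was -0.30 without CRISPRi mouse 3, and that of fatty acid synthesis was -0.046 without non-targeting mouse 1 and -0.37 without non-targeting mouse 3, and -0.45 with median-of-ratios scaling.

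Lists of mature hepatocyte products passed in the lower direction as well. Plasma proteins had a median log2 fold change of -0.41 with 36 of 43 members below 0, and acute phase genes had -0.63 with 27 of 33 below 0. C9, a component of the membrane attack complex, had a mean TPM 3.78-fold lower in the CRISPRi mice (log2 fold change -1.76, SE 0.38), C8b had a log2 fold change of -1.19 and C8a one of -2.93. Serpina1c had -1.72, Crp -1.18, Ifitm3 -1.16 and Serpina3k -0.63, while Cebpd, a transcription factor gene of the acute phase list, had 0.58. The groups did not overlap for 13 lower and 2 higher plasma protein genes and for 11 lower and 2 higher acute phase genes. Adjusted over the list alone, 3 plasma protein genes passed, all lower, and 0 acute phase genes. Non-targeting mouse 2 had the highest mean of the acute phase list, at 8.21, against 6.84 and 6.76 in the other controls and 6.53 to 6.72 in the CRISPRi mice. The camera adjusted p was 1.16e-16 for plasma proteins and 2.12e-12 for acute phase, and 0.386 for both with an estimated correlation. Without non-targeting mouse 2 the medians were -0.15 for plasma proteins and -0.20 for acute phase genes, and without non-targeting mouse 3 that of plasma proteins was -0.63, as it was with median-of-ratios scaling.

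Drug metabolism and sex-biased genes showed the same direction in camera. In the cytochrome P450 and xenobiotic list the median was -0.08, 25 of 48 members were below 0 and 9 passed adjusted over the list alone, all lower. The summed TPM of that list was not lower in the CRISPRi mice (log2 ratio of the means 0.095, exact two-sided permutation p = 0.6). Cyp2j5 had a log2 fold change of -2.29, Cyp2c54 -1.84, Ugt2b1 -1.38 and the carboxylesterase gene Ces1d -1.07. The male-biased list had a median of -0.55 and 4 genes that passed adjusted over the list alone, all lower. The major urinary protein genes Mup3, Mup20 and Mup21 had log2 fold changes of -3.50, -2.05 and -1.22. The female-biased list had a median of -0.53 and 5 such genes, all lower. The sulfotransferase genes Sult2a1 and Sult2a5 had -2.12 and -1.81, Cyp3a41a had -2.66 and Cyp2c40 had -1.58. Adjusted p in camera was 4.79e-07, 1.08e-10 and 6.16e-10 for these 3 lists, and with an estimated correlation the adjusted p was 0.239, 0.386 and 0.152. The mean of the male-biased list in non-targeting mouse 1, 4.13, lay within the CRISPRi range of 2.96 to 4.40, with 5.48 and 5.64 in the other controls, and its median was -0.89 without that mouse and -0.23 without CRISPRi mouse 3. The median of the drug metabolism list was -0.0021 without non-targeting mouse 1, -0.13 without non-targeting mouse 3 and -0.28 with median-of-ratios scaling, and that of the female-biased list -0.32 without non-targeting mouse 2. Mup, Sult2a, Cyp2c, Cyp3a and Serpina1 genes have near-identical paralogs, so the division of reads among their members is uncertain.

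Smaller shifts to lower levels were called for 3 lists of liver function. Amino acid catabolism passed at an adjusted p of 6.74e-04 (0.800 with an estimated correlation) although its median log2 fold change, 0.07, was opposite in sign to the test, and its mean was -0.01. Prodh2, Afmid and the histidase gene Hal had log2 fold changes of -0.73, -0.88 and -0.58. Periportal genes passed at 3.62e-04 (adjusted p = 0.386 with an estimated correlation) with a median of -0.05, and Cyp2f2 had -1.15. Growth hormone and hepatokine genes passed at 0.00971 (adjusted p = 0.386 with an estimated correlation) with a median of 0.03 and a mean of 0.02, both opposite in sign to the test. Their members went both ways, with the mean TPM of Igfals 1.96-fold and of Hgfac 2.24-fold lower, and the insulin-like growth factor binding protein gene Igfbp1 at a log2 fold change of 1.89 and Fgf21 at 1.04. With median-of-ratios scaling the medians of amino acid catabolism and of growth hormone genes became -0.14 each, and the latter list no longer passed, while the median of periportal genes became -0.26. Without non-targeting mouse 1 amino acid catabolism no longer passed, nor did periportal genes with median-of-ratios scaling as well (adjusted p = 0.0511), and without non-targeting mouse 2 the growth hormone list did not. The medians of these 3 lists also changed sign with single mice. That of periportal genes was 0.097 without non-targeting mouse 1 and 0.033 without CRISPRi mouse 1. That of amino acid catabolism was -0.069 without non-targeting mouse 2, -0.11 without non-targeting mouse 3 and -0.063 without CRISPRi mouse 3, and that of growth hormone genes was -0.041 without non-targeting mouse 3 and -0.026 without CRISPRi mouse 2.

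Among the lists called higher, targets of NRF2 and oxidative stress had a median log2 fold change of 0.72, and 39 of 42 members lay above 0. The autophagy receptor gene Sqstm1 had a mean TPM of 1815 ± 285 against 854 ± 397 (SD, n = 3 each). The cystine transporter gene Slc7a11 had a log2 fold change of 1.68, Akr1b7 had 1.75 and Akr1b8 had 0.84. Adjusted over the list alone, 1 gene passed, higher. The list means were 8.54 in non-targeting mouse 1 and 8.46 to 8.68 in the CRISPRi mice, against 7.37 and 7.81 in non-targeting mice 2 and 3, and without non-targeting mouse 1, 26 members passed in limma over all genes, all higher. The median was 0.39 without non-targeting mouse 2. The camera adjusted p was 2.01e-05, and 0.803 with an estimated correlation.

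YAP targets had a median of 0.50 with 18 of 19 members above 0, and 3 passed adjusted over the list alone, all higher. Nt5e, which encodes the ectonucleotidase CD73, had a log2 fold change of 1.20, Ptpn14 had 1.30, Axl 0.58 and Myof 0.57. Targets of p53 had a median of 0.47 with 25 of 28 members above 0, and none passed adjusted over the list alone. Counts above 0 do not set these lists or the NRF2 list apart, since all tested genes had a median of 0.18. Among lists not called, 30 of 31 proteasome and 17 of 19 heat shock genes were above 0. Mdm2 had a log2 fold change of 0.68, Ccng1 0.59, Phlda3 0.85 and Aen 0.42. The adjusted p in camera was 3.56e-04 for YAP targets and 0.0350 for p53 targets, and with an estimated correlation the adjusted p was 0.713 and 0.894. The means in non-targeting mouse 1, 2.26 for YAP and 4.03 for p53 targets, lay within the CRISPRi ranges of 2.24 to 2.54 and 3.79 to 4.12, with 1.55 and 1.78, and 3.09 and 3.47, in non-targeting mice 2 and 3. The p53 list no longer passed without non-targeting mouse 2, where its median was 0.24, or without CRISPRi mouse 2, and its median was 0.73 without non-targeting mouse 1 and 0.29 with median-of-ratios scaling.

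**Figure D3:**
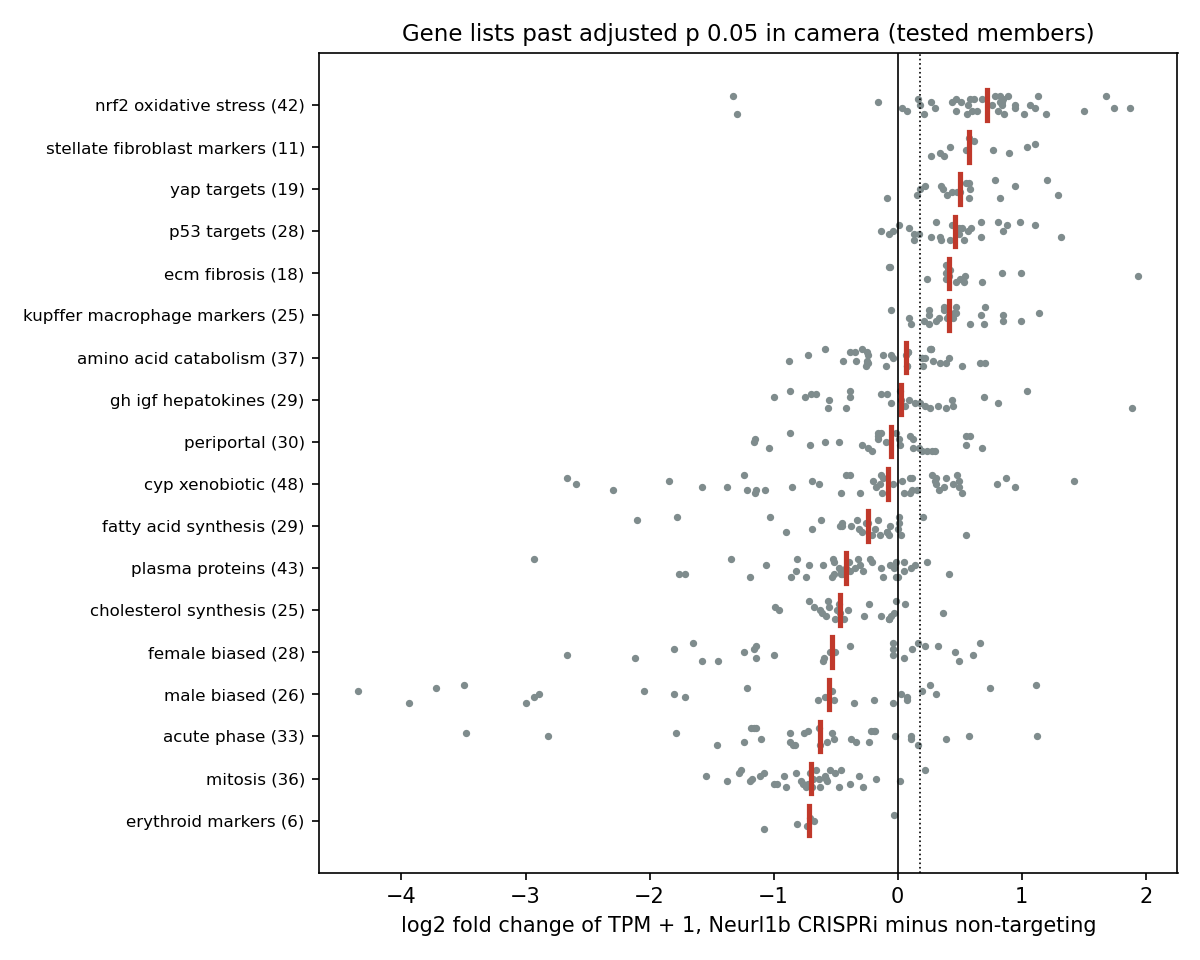
Log2 fold change of TPM + 1 (horizontal axis, Neurl1b CRISPRi minus non-targeting) of the tested members of the 18 lists past an adjusted p of 0.05 in camera with the preset correlation. Grey points are genes, red bars list medians, the solid line is 0 and the dotted line the median of all tested genes, 0.18; mitosis genes have a median of -0.70 and NRF2 targets one of 0.72, and the highest medians belong to the lists called higher.

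Because the pulldown started from whole liver, markers of other cell types were measured in the same libraries. Stellate cell and fibroblast markers were higher in every CRISPRi mouse than in any control, with a list mean of 2.65 against 2.02 on the log2 scale and 7 of 11 genes past the threshold adjusted over the list alone, all higher. Reln, Cygb, Dcn and Ecm1 had log2 fold changes of 0.90, 0.77, 1.04 and 1.11. Kupffer cell and macrophage markers had a list mean of 3.41 against 2.94, and Csf1r, Spi1, Vsig4 and Cd9 had log2 fold changes of 0.85, 0.59, 0.67 and 0.99. The exact two-sided permutation p was 0.1 for both, the smallest possible. Extracellular matrix genes had a median of 0.41 and 4 that passed adjusted over the list alone, all higher, and Lgals3, Timp3, Bgn and Timp2 had log2 fold changes of 1.94, 0.84, 0.68 and 0.54. In camera the adjusted p was 1.40e-05 for stellate, 8.66e-04 for Kupffer and 0.00139 for matrix genes, and with an estimated correlation the adjusted p was 0.386, 0.713 and 0.594. None of these 3 lists passed camera without non-targeting mouse 1 (adjusted p of 0.0542 for stellate markers). In that fit the medians were 0.61 for stellate, 0.31 for Kupffer and 0.47 for matrix genes, against 0.29 for all tested genes. Without non-targeting mouse 2 the medians were 0.38 for stellate and 0.26 for matrix genes, against 0.58 and 0.41 with all mice.

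Erythroid markers moved with a single control mouse. Their list mean was 7.38 in non-targeting mouse 2, and 5.05 to 6.12 in the other 5 libraries (exact two-sided permutation p = 0.5). The list passed camera in the lower direction (adjusted p = 4.41e-04, 0.514 with an estimated correlation, median -0.72) but not without that mouse, where the median was -0.077, and without CRISPRi mouse 2 it was -0.23. Alas2, an enzyme of haem synthesis in red cell precursors, had a log2 fold change of -1.07. Endothelial markers (camera adjusted p = 0.0527, median 0.30), leukocyte markers (0.0836, median -0.18) and cholangiocyte markers (0.563, median 0.22) did not pass, and the exact two-sided permutation p of their list means was 0.2, 0.6 and 0.3. In 20 alternatives, endothelial markers passed in 6, higher, and leukocyte markers in 5, lower. With median-of-ratios scaling these medians became 0.18, -0.38 and 0.011, and that of Kupffer markers went from 0.41 to 0.24. Without non-targeting mouse 1 the endothelial, leukocyte and cholangiocyte medians were 0.30, -0.29 and 0.45. The endothelial genes Bmp2 and Cldn5 had log2 fold changes of 0.66 and 0.56. The 10 most abundant genes held 17.84% ± 1.71 of the TPM in the controls and 16.18% ± 1.43 in the CRISPRi mice (SD, n = 3 each, exact two-sided permutation p = 0.3).

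The Notch pathway, in which Neurl1b acts, was not called. Notch components had a camera adjusted p of 0.637 and a median log2 fold change of 0.12, which became -0.05 with median-of-ratios scaling. Notch targets had 0.385 and 0.33, a median opposite in sign to the test, with 4 members below 0 and 5 above. None of the 26 tested components or 9 tested targets passed in limma, over all genes or adjusted over the list alone. Without non-targeting mouse 1, 4 components and 2 targets passed over all genes, all higher, and the medians were 0.25 and 0.73. In that fit 2436 of 10558 genes passed as higher, so these counts do not set the 2 lists apart. Without non-targeting mouse 2 the target list passed camera in the lower direction. Neurl1a, the closest relative of Neurl1b, had a mean TPM of 2.35 ± 0.820 against 0.896 ± 0.305 (SD, n = 3 each), a log2 fold change of 0.80 (SE 0.22, adjusted p = 0.323 in limma). Neurl2 had -0.47, the endocytic adaptor gene Numbl 0.53 and Kcp, a regulator of BMP signalling, 0.88. The targets Hes1, Hes6 and Sox9 had log2 fold changes of -0.41, -0.52 and -0.35, and Myc and Ccnd1 had 0.92 and 0.80, each with an unadjusted p above 0.05. The further tested members Neurl3, Mib1, Mib2, Dll1, Rbpj, Maml1, Rfng, Adam10, Adam17, Psen2, Ncstn, Aph1a, Psenen, Numb, Pofut1, Poglut1, Fbxw7, Itch, Dlk1, Spen, Snw1, Spp1, Id1, Id3 and Gata3 also had an unadjusted p above 0.05. The receptors Notch1, Notch2, Notch3 and Notch4, the ligands Jag1, Jag2, Dll3 and Dll4, and Maml2, Maml3, Lfng, Mfng, Aph1b, Hey1, Hey2, Heyl, Nrarp, Dtx1, Dtx3, Il2ra, Trib2, Hes2, Hes5 and Hes7 had a mean TPM below the filter.

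Several lists that camera did not call held members that passed adjusted over the list alone. Fetal and dedifferentiation genes had 7 of 23, all higher, with a median log2 fold change of 0.48 and a list adjusted p of 0.0524, and the list passed in 9 of 20 alternatives. Alpha-fetoprotein, Afp, had a mean TPM of 252 ± 80.9 against 98.6 ± 33.7 (SD, n = 3 each), and Anxa2, the proteoglycan gene Gpc3 and Cd24a had log2 fold changes of 1.34, 1.06 and 0.99. The unfolded protein and integrated stress response list had 7 of 38, all higher (list adjusted p = 0.220, median 0.20, and 0.019 with median-of-ratios scaling), with Ddit4 at 1.29, Nupr1 at 0.90, Psat1 at 0.80 and Fgf21 at 1.04. Immediate early genes had 4 of 24 in both directions (list adjusted p = 0.0960, median 0.50, passed in 6 of 20 alternatives), with Dusp1 at 1.04, Jund at 0.65, Egr1 at -1.54 and Ier2 at -0.68. Fatty acid oxidation had 1 of 42 (list adjusted p = 0.549, median 0.18, and -0.03 with median-of-ratios scaling). Fabp1, the liver fatty acid binding protein gene, had a mean TPM 3.57-fold lower (log2 fold change -1.83, SE 0.35), while Ehhadh and Acaa2 had log2 fold changes of 1.01 and -0.45. Without non-targeting mouse 1 the median was 0.33 for fatty acid oxidation and 0.34 for the unfolded protein and integrated stress response list.

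The remaining lists did not pass camera, and none of their members passed adjusted over the list alone. Bile acid genes had an adjusted p of 0.464, with the bile salt transporter genes Slc10a1 at a log2 fold change of -0.70 and Abcc3 at 0.75. Tyrosine catabolism had 0.224, gluconeogenesis and urea cycle 0.225, pericentral and WNT genes 0.563 and hepatocyte transcription factors 0.0917. Interferon genes had an adjusted p of 0.0836, heat shock genes 0.710, circadian genes 0.582 and endocytosis and ubiquitin genes 0.240. Mitochondrially encoded genes had 0.529, oxidative phosphorylation 0.549, ribosomal proteins 0.385, ribosome biogenesis 0.419 and the proteasome 0.158.

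CRISPRi can reach neighbouring promoters, so the 5 tested genes nearest Neurl1b on each side were examined, taking their order from the GRCm38 annotation. None of the 10 passed in limma, and 3 had an unadjusted p below 0.05, all higher. Dusp1, the nearest on one side, had a mean TPM of 11.8 ± 1.63 against 5.47 ± 2.52 (SD, n = 3 each), and Atp6v0e, Arhgdig and Fam234a had log2 fold changes of 0.75, 0.76 and 0.39. The groups did not overlap for these 4, and did for Ergic1, Crebrf, Bnip1, Luc7l, Axin1 and Mrpl28. Without non-targeting mouse 1, 2 of the 10 passed, Dusp1 and Atp6v0e, in a fit where 2673 of 10558 genes passed.

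The groups overlapped for both products carried by the plasmid, and neither passed in limma (adjusted p = 0.918 for Fah and 0.668 for Rpl10a). Fah had a mean TPM of 63.9 ± 9.74 in the controls and 62.5 ± 14.9 in the CRISPRi mice, and Rpl10a, whose signal combines the endogenous and the tagged gene, had 1047 ± 58.5 and 964 ± 98.8 (SD, n = 3 each). The Y-linked genes were detected in all 6 libraries, with a TPM of 11.3 to 19.1 for Ddx3y, 19.3 to 35.7 for Eif2s3y, 0.587 to 1.30 for Uty and 0.236 to 0.497 for Kdm5d. Xist was not among the symbols of the table.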

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

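The fit without non-targeting mouse 1 and with median-of-ratios scaling was chosen after seeing the data, as was the use of unfiltered fits for Neurl1b. All others were chosen before. The direction of Neurl1b held in all 16 alternatives, with unadjusted limma p of 2.60e-04 to 0.0156. Its log2 fold change was -1.28 with a pseudocount of 0.1, -0.16 with one of 5, and -0.65 to -0.44 in the others. A filter of mean TPM of at least 5 gave no value for it. Of genes changed, 2 passed in limma. The count was 0 with a pseudocount of 5 (1404 at an unadjusted p below 0.05), with no filter (0, 2132 unadjusted), with quantile normalization (0, 1403 unadjusted) and in the transcript-level test (0, 1938 unadjusted). It was 1 with a filter of mean TPM of at least 5 (Gm9385), which Plekhb2 did not pass. With array weights it was 2210, 1963 of them higher. Leaving out each mouse gave 0 (without non-targeting mouse 3, 920 unadjusted) to 2673 (without non-targeting mouse 1), and 480 without that mouse and with median-of-ratios scaling. The causes of the other losses of calls were not tested. Without CRISPRi mouse 1 or mouse 2 the count was 4, with Gm15770 and Gm8399, or Gstp3 and Gstp-ps, besides Plekhb2 and Gm9385. At an adjusted p of 0.1, 3 passed, Rps24-ps3 being the third. Plekhb2 had log2 fold changes of 1.35 to 3.95 and adjusted p of 0.00484 to 0.226.

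Of 42 lists, 18 passed, 15 to 23 under every camera setting with the preset correlation except 0 with an estimated correlation, and 0 in fry; no called list changed direction. Mitosis, cholesterol and fatty acid synthesis, plasma protein, acute phase, cytochrome P450, NRF2 and both sex-biased lists passed in all 18 of those camera fits. These fits share the preset correlation and most of the libraries, so they are not independent support, and none of these lists passed with an estimated correlation. With a filter of mean TPM of at least 5 the p53, YAP and matrix lists no longer passed, with array weights the matrix and Kupffer lists, and with quantile normalization the growth hormone list. Of the 24 lists not called, 16 passed in at least 1 setting, 52 times in all: fetal in 9, endothelial and immediate early in 6, leukocyte in 5, ribosomal and proteasome in 4, and the other 10 in 1 to 3. Of the 10 genes near Neurl1b, 0 passed, against 2 with array weights, and leaving out each mouse gave 0 to 2, with 1 when non-targeting mouse 1 was left out with median-of-ratios scaling. The differences of cell type marker means kept their sign in summed TPM and without each mouse. Of 1994 values of 113 named genes, 1732 kept their direction and side of the threshold, 250 passed in addition (with array weights or, but for 1, without non-targeting mouse 1), 8 lost their call (Plekhb2 and Gm9385) and 4 changed sign. These belong to Fah, which had log2 fold changes of 0.18 with array weights, 0.039 without non-targeting mouse 2, 0.065 without CRISPRi mouse 1 and 0.030 without CRISPRi mouse 3, against -0.045 with all mice and -0.23 without CRISPRi mouse 2.

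The mouse numbers do not pair the samples: same-numbered mice had correlations of deviations of 0.06, -0.10 and -0.28. With the number as a replicate block, 2 genes, 21 lists and 0 of the genes near Neurl1b passed, and Neurl1b had a log2 fold change of -0.55. Depth is unknown, so the precision of low values such as that of Neurl1b is not known.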

Other observations

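Chosen after the results were seen were the tests of symbol-stem families, the divisions of the libraries, the Neurl1b level as a check of the label of non-targeting mouse 1, the fit without that mouse and with median-of-ratios scaling, the use of scaling and of the fit without non-targeting mouse 2 to weigh the mitosis list, and the searches for similar transcripts. Genes were grouped by a shared symbol stem, which gave 263 families of 6 to 69 tested members, and 6 families passed an adjusted p of 0.05 in camera with the preset correlation, all lower in the CRISPRi mice. Major urinary protein genes (Mup) had a median log2 fold change of -2.03 with 17 of 19 members below 0. Serpina genes had -0.53 with 13 of 15, and carboxylesterase genes (Ces) -0.46 with 10 of 13. The groups did not overlap for 3 of 19 Mup genes, near the 17.05% of all tested genes, and for 7 Serpina and 6 Ces genes, all lower. Mup genes have near-identical paralogs, so their division of reads is uncertain. Cytochrome P450 (Cyp), sulfotransferase (Sult) and N-acetyltransferase (Nat) genes had medians of -0.04, -0.50 and -0.20. Sult and Nat no longer passed with median-of-ratios scaling (adjusted p = 0.129 and 0.0609), and every family had an adjusted p of 0.999 with an estimated correlation. Myosin-stem genes (Myo), with a median of 0.65 and 11 of 12 members above 0, had an adjusted p of 0.0567, and of 0.0191 with median-of-ratios scaling.

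The number of genes and lists called was compared with the other divisions of the 6 libraries into 3 and 3, of which there are 10 with the real one, too few for a share under 0.05. The real division called 2 genes, and the highest of the others 2, so that 2 of 10 called as many. The real division called 18 lists with the preset correlation, the highest of the others 26, and 8 of 10 called at least as many. With an estimated correlation 0 lists were called in every division. The division that set non-targeting mouse 1 and CRISPRi mice 1 and 2 against the rest gave 2194 genes at an unadjusted p below 0.05, against 1408 for the real one.

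Non-targeting mouse 1 lay near the CRISPRi mice, and 2673 genes were called without it, 91.1% of them higher. Its mitochondrially encoded genes had a list mean of 5.58, against 6.32 to 7.01 in the other libraries. A wrong label is argued against by Neurl1b, at 1.22 TPM in that library and at most 0.351 in the CRISPRi libraries. Median-of-ratios scaling, which removes only a single factor per library, still left 480 genes called, of which 39.38% were higher. This argues against such a factor as the whole cause of the number called. The number and the share higher both fell with the scaling, so library composition stays open as part of the cause. A difference in the state of the 3 control mice, or an effect of the guide hidden by that mouse, stays open as untested.

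Mitosis genes were lower in the CRISPRi mice in the list fixed beforehand, while the DNA replication list was not called with all mice. The mitosis call was lost with an estimated correlation (camera, adjusted p = 0.386) and in fry (adjusted p = 0.338). The list's median log2 fold change was -0.89 with median-of-ratios scaling and -0.70 without it. That scaling lowered every list median, so the lower value was bound to follow and does not test library composition. The median of all tested genes, 0.18 without scaling, lay in the other direction, so a shift shared by all genes does not account for the lower mitosis list. Without non-targeting mouse 2, where haemoglobin was highest, the difference of the mitosis list means was -0.85, while the erythroid difference shrank from -0.67 to -0.17. The mitosis difference therefore did not rest on that mouse. This cannot decide on RNA of dividing erythroid cells, since the erythroid list holds globin genes. Alas2, a gene of red cell precursors, kept a log2 fold change of -0.72 or lower in every alternative, so that source stays open. A hypothesis left open is that fewer hepatocytes were in mitosis in the CRISPRi livers, which may equally reflect when each liver was sampled in repopulation, and neither was tested.

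Plekhb2 and Gm9385 were the called genes. Gm9385 is 99.79% identical to Rpl24 over its whole length, so reads of Rpl24 are a candidate source of its level. That alone leaves the group difference open, since Gm9385 made up at most 2.22e-04% of the summed TPM of both in the controls and 0.447% to 1.14% in the CRISPRi mice, with Rpl24 at 1084 to 1174 and 1184 to 1230 TPM. For Plekhb2, reads of a similar gene are argued against, since matches to other genes at 90% identity or more covered 0% of the 3279-nt transcript that held 88.9% of its TPM. A sequence difference between the mice at either gene, and an off-target or a downstream effect of the guide, stay open as untested.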
